A study of Arabidopsis thaliana with 42 samples.

How the data were processed

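Total RNA and small RNA of wild-type Arabidopsis thaliana leaves were analysed from processed tables, with 28 total RNA libraries (14 ages, 2 sets) and 14 small RNA libraries (7 ages, 2 sets). Per the submitters' description the libraries were sequenced on an Illumina HiSeq instrument, and their processing notes name TopHat 1.4.0, Cufflinks and the TAIR10 genome for every library, without saying how they were applied to small RNA. Total RNA values are FPKM per transcript, as the authors deposited them. Small RNA values are raw read counts per sequence, deposited by the authors separately for each set. How adapters were trimmed and which sequences were kept in the small RNA tables is not given in the sources used here.

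The total RNA tables list 41673 transcripts, which were summed to 33604 genes; 32835 of these were matched to reference names. Of the genes, 133 are chloroplast-encoded and 146 mitochondria-encoded, with 6 and 13 of them listed at 0 in every library. The small RNA tables hold 111188 (set 1) and 158221 (set 2) entries, many of them repeats, for 70458 and 103406 distinct sequences of 18 to 48 nt in DNA letters, each with at least 5 counts in its library of second-highest count. Of the entries, 115 and 114 are in RNA letters, and 13242 and 21868 sequences are listed together with their reverse complement, with different counts in only 4 and 2 of those pairs. Entries in RNA letters were set aside, repeats with the same counts were used once, and each pair was collapsed to 1 feature; where a feature had 2 different sets of counts (159 and 153 features) these were summed. This left 57216 and 81538 features, and the features listed in both tables (53340 of 85414) were used. The strand of a feature is therefore unknown. MicroRNA families were identified by exact match to mature sequences fixed beforehand; 28 of 29 were found, and miR397 was not.

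Read depth cannot be read from FPKM. Small RNA depth was taken as the sum over listed features, between 4905408 and 9713665 reads per library; sequences under the listing limit are not in this sum. With pseudocount 1, genes near or under 1 FPKM show compressed changes.

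Young, mature and old stages were fixed before the data were examined, as were the tests, 34 gene lists (555 genes, 521 measured), microRNA sequences, microRNA targets and the rule for named genes. In the total RNA log2(FPKM + 1) of the 18239 genes with at least 1 FPKM in at least 2 libraries was fitted with limma 3.58.1 (trend), with day as a factor and the set as a block. Stage contrasts compare the means of 3 days, and an F test covers all days. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05, and again over each list alone. Lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the 34 lists. Small RNA counts of the 46841 features with at least 10 counts in at least 2 libraries were tested with edgeR 4.0.16 (quasi-likelihood, TMM factors, set as a block). Counts of the 1 mature sequence of each family were tested in the same way, with library sizes from all features. Shares of summed FPKM, with rRNA and tRNA genes left out, were compared by exact permutation within sets (400 arrangements, smallest p = 0.005). Shares of read lengths were compared by exact permutation over both sets (70 arrangements, smallest p = 0.0286), since within sets the smallest p is 0.0556. MicroRNA and target levels were correlated over 14 pairs of libraries with 100000 permutations of days within sets, adjusted over 45 pairs. Work was done in R 4.3.3 with DESeq2 1.42.0 and data.table (version 1.17.8) and in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

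Genes named in the text are the 10 largest rises and 10 largest falls per comparison among protein-coding genes that passed with the same direction in both sets, and members of the lists. Sequences named are the 5 largest rises and falls by the same rule. The lists are: cell cycle and DNA replication, cell wall expansion, cytosolic ribosomal proteins, stomatal lineage and guard cells, vascular tissue, shoot meristem and flower, circadian clock, heat shock, leaf growth, chlorophyll synthesis, chlorophyll breakdown, antenna, nuclear-encoded photosystems and electron transport, chloroplast-encoded photosystems and cytochrome complex, chloroplast-encoded NDH complex, chloroplast-encoded gene expression, plastid transcription machinery, Calvin-Benson cycle, mitochondria-encoded respiration, mitochondria-encoded gene expression, alternative respiration, autophagy, beta-oxidation and glyoxylate cycle, proteases, nitrogen remobilization, anthocyanin synthesis, NAC and WRKY regulators, senescence-associated markers, abscisic acid, ethylene, jasmonate, salicylic acid and defence, cytokinin, and small RNA machinery.

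The models were tested on simulated data with 200 changed genes, drawn from those with higher levels, and without a set effect. In the small RNA 1 dispersion was used for all sequences. Of 100 genes changed by 1 on the log2 scale, 89 were called in each comparison of the total RNA design, and of 100 changed by 2, 100 were called in mature against young and 99 in old against mature leaves, with 11 wrong calls. In the small RNA design, with a dispersion of 0.2564, 0 of 100 were called at a log2 change of 1 (edgeR). At a log2 change of 2, 20 were called in mature against young and 16 in old against mature leaves.

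Alternatives fixed beforehand were no set block, a pseudocount of 0.1, no filter (28173 genes, 53340 features), rescaling to the nuclear sum, quantile normalization, narrower stages, each set alone, DESeq2 size factors, DESeq2, all features listed in at least 1 of the tables (54372), reads without microRNA sequences, an estimated correlation, correlations without the 2 farthest pairs, and each library left out in turn. Chosen after the data were seen were leaving out day 4, reads of 18 to 28 nt alone (33532 features), shares of 20 to 24 nt reads, shares of the nuclear sum, permutation within sets for read lengths, leaving out the 10 most abundant sequences, families from RNA letters, the class of 29 to 33 nt, the summing of transcripts and the collapsing of repeated sequences. Reads of rRNA and tRNA are not labelled in the small RNA, and the sequences were not matched to rRNA or tRNA genes, so their removal was not run.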

Results

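The RNA of Arabidopsis thaliana leaves was followed through the life of the leaf, with age given in days after emergence. Total RNA was sequenced at 14 ages, every 2 days from day 4 to day 30, and small RNA at 7 ages, every 4 days from day 4 to day 28. Each age was sampled in 2 sets, which gave 28 total RNA and 14 small RNA libraries. The submitters call the sets independent biological replicates without saying what was separate, so p-values measure the spread between these libraries, which may be partly technical. The total RNA of days 4, 6 and 8 was taken as young, of days 14, 16 and 18 as mature and of days 26, 28 and 30 as old, with 6 libraries each. In the small RNA the young stage was days 4 and 8, the mature stage days 12 and 16 and the old stage days 24 and 28, with 4 libraries each. The read depth behind the total RNA values is unknown, since they are FPKM; summed FPKM was 331479 in the day 4 library of set 1 and between 439949 and 484348 in the others. The listed small RNA sequences held between 4905408 reads (day 12, set 1) and 9713665 reads (day 4, set 2).

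Nearly every gene tested varied with leaf age. Over the 14 days, 16605 of 18239 genes changed (limma F test at an adjusted p of 0.05). The mean level was highest at day 30 in 4980 genes, at day 28 in 1954 and at day 6 in 1804, but at day 18 in only 151. Between neighbouring ages most change fell at the ends of the series. From day 28 to day 30, 5626 genes changed, 3982 of them downwards, and from day 26 to day 28 another 1529 did. From day 4 to day 6, 2084 genes changed, of which 2026 rose, whereas none of the 7 steps between day 6 and day 20 changed more than 25 genes. The step from day 4 includes the library of set 1 that stood apart with low values (next paragraph). Its changes can therefore not be read as leaf age alone. Each step sets 2 libraries against 2. The count from day 28 to day 30 was 3360 without the day 28 library of set 1, 3504 without that of set 2, 3016 without the day 30 library of set 1 and 8288 without day 4, and without the day 4 library of set 2 the step from day 4 to day 6 held the most changes, 10891.

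The day 4 library of set 1 stood apart from the other young libraries. It held 13359 genes at 1 FPKM or above, against 15335 in the day 4 library of set 2. Ribosomal RNA genes took 2.64% of its FPKM and 0.0308% of that of its counterpart, mitochondria-encoded genes 1.71% and 0.988%, and chloroplast-encoded genes 23.8% and 19.7%. Across tested genes, which are not independent replicates, the day 4 libraries correlated at r = 0.934, while the 2 libraries of the other days correlated at 0.976 to 0.990.

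The first comparison asked how transcripts differ between young and mature leaves. Levels below are mean FPKM ± SD over 6 libraries, and changes are differences of mean log2(FPKM + 1) ± SE, a scale that understates the change of weakly expressed genes. The largest rise was that of GolS2 (AT1G56600), a galactinol synthase, from 0.633 ± 0.698 to 57.3 ± 16.0 FPKM (5.23 ± 0.18, adjusted p = 5.12e-13, limma). ORS1 (AT3G29035), a NAC transcription factor that promotes senescence, rose from 0.0787 ± 0.0691 to 30.4 ± 12.7 FPKM (4.79 ± 0.15, adjusted p = 1.63e-13). The pathogenesis-related glucanase gene PR2 (AT3G57260) rose from 1.25 ± 1.05 to 65.9 ± 76.3 FPKM (4.44 ± 0.29, adjusted p = 8.76e-10), and CAX3 (AT3G51860), a vacuolar cation exchanger, from 0.183 ± 0.124 to 24.0 ± 11.1 FPKM (4.28 ± 0.21, adjusted p = 2.17e-11). PCR1 (AT1G14880), LURP1 (AT2G14560), IMS2 (AT5G23020), AT1G34060, AT1G76960 and AT5G18130 made up the rest of the 10 largest rises, with changes of 4.14 to 4.88. Among the falls, AT5G48490 went from 145 ± 21.4 to 2.11 ± 1.15 FPKM (-5.62 ± 0.21, adjusted p = 1.16e-12) and the germin-like gene GER3 (AT5G20630) from 64.5 ± 50.8 to 0.507 ± 0.157 FPKM (-5.06 ± 0.15, adjusted p = 1.63e-13). HTH (AT1G72970), which acts in cuticle formation, fell from 35.1 ± 10.6 to 1.62 ± 0.467 FPKM (-3.75 ± 0.14, adjusted p = 1.16e-12), and the lipase gene LTL1 (AT3G04290) from 27.5 ± 23.9 to 0.0471 ± 0.0426 FPKM (-4.19 ± 0.22, adjusted p = 6.49e-11). AT3G16670, AT4G28780, AT5G45670, AT2G10940, AT3G54400 and GPAT3 (AT4G01950) were the others, with changes of -4.69 to -3.66. All 20 moved the same way in both sets, as the rule for naming them required.

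In all, 9406 genes were higher and 3049 lower in mature than young leaves. The median change of all tested genes was itself 0.32; a list median called relative has the median of all tested genes subtracted, and other medians are as measured. Higher calls were 75.5% of all calls as deposited but 54.3% after quantile normalization (6397 higher, 5390 lower); without day 4 there were 8600 higher and 3633 lower.

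Genes of dividing and expanding tissue were lower in mature leaves. Of 19 measured genes of the cell cycle and DNA replication, 18 fell, 0 rose and 1 did not pass, with a relative median of -1.51. MCM6, a subunit of the replicative helicase, fell from 2.45 ± 0.672 to 0.322 ± 0.144 FPKM (-1.37 ± 0.08), PCNA1 from 5.82 ± 2.53 to 0.949 ± 0.519 (-1.77 ± 0.18) and the cyclin CYCD3;1 from 3.89 ± 1.38 to 0.786 ± 0.233 (-1.42 ± 0.14). The list passed limma's camera test (adjusted p = 1.93e-14; adjusted p = 0.228 with an estimated correlation). For cell wall expansion, 8 of 13 genes fell, among them EXPA5 (35.1 ± 11.5 to 6.80 ± 2.61 FPKM) and XTH9 (13.9 ± 6.96 to 2.17 ± 0.967), 4 did not pass and EXPA1 rose (0.85 ± 0.28, adjusted p = 0.012; adjusted p = 0.0537 without the day 4 library of set 1, 0.0528 without the day 14 library of set 1 and 0.28 without day 4). This list had a relative median of -1.54 (camera adjusted p = 1.5e-05; adjusted p = 0.376 with an estimated correlation). All 17 cytosolic ribosomal protein genes fell, RPS6A from 118 ± 34.3 to 33.8 ± 5.95 FPKM (-1.74 ± 0.11) and RPL5A from 154 ± 32.1 to 62.6 ± 13.1 (-1.28 ± 0.12), with a relative median of -1.17 (camera adjusted p = 9.19e-12; adjusted p = 0.245 with an estimated correlation).

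Stomatal markers fell as well, while vascular markers went both ways. Of 6 measured genes of the stomatal lineage and guard cells, 5 fell, among them TMM (5.18 ± 3.80 to 0.472 ± 0.155 FPKM) and EPF1 (2.29 ± 0.863 to 0.378 ± 0.265), and 1 did not pass. The list had a relative median of -1.38 (camera adjusted p = 0.000292; adjusted p = 0.228 with an estimated correlation). Of 8 vascular genes, 4 fell, 3 rose and 1 did not pass. The relative median of the list was -1.04 (camera adjusted p = 0.00938; adjusted p = 0.523 with an estimated correlation). The falls included the cellulose synthases of the secondary wall IRX5 (5.07 ± 0.984 to 0.920 ± 0.354 FPKM) and IRX3 (3.25 ± 0.825 to 0.644 ± 0.313), while the phloem sucrose transporter SUC2 rose from 137 ± 39.6 to 197 ± 20.4 FPKM (adjusted p = 0.0017; adjusted p = 0.0729 without day 4). Of the 11 genes of shoot meristem and flower only 3 were measured, of which SEP3 rose (0.278 ± 0.138 to 0.654 ± 0.272 FPKM), and the list did not pass. This gave the list a relative median of -0.13 (camera adjusted p = 0.95). In the circadian clock list, fixed as a sign of the time of harvest, 8 of 9 genes rose, LHY from 11.8 ± 4.19 to 41.6 ± 10.6 FPKM and CCA1 from 26.7 ± 9.76 to 56.0 ± 7.19, and 1 fell. As a group these genes had a relative median of 0.52 (camera adjusted p = 0.11). Among 6 heat shock genes, listed as a sign of handling stress, 2 rose, HSP70 from 1.38 ± 0.463 to 4.45 ± 2.3 FPKM, 1 fell and 3 did not pass; the median change of 0.07 and the mean of 0.37 were positive while camera pointed downwards (adjusted p = 0.977).

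Transcripts of the plastid genetic system and of chlorophyll synthesis were lower in mature leaves. Of 17 genes of chlorophyll synthesis, 15 fell, 0 rose and 2 did not pass. The members had a relative median of -1.12 (camera adjusted p = 2.82e-11; adjusted p = 0.228 with an estimated correlation). DVR fell from 61.0 ± 9.27 to 15.8 ± 4.57 FPKM (-1.92 ± 0.12), CHLI1, a subunit of magnesium chelatase, from 276 ± 41.7 to 101 ± 18.0 (-1.44 ± 0.11) and PORA from 5.0 ± 0.864 to 0.80 ± 0.317 (-1.74 ± 0.10). Among 27 chloroplast-encoded genes of transcription, splicing and translation, 20 fell, 6 did not pass and rpoC1 rose (0.57 ± 0.12), with a relative median of -1.27 (camera adjusted p = 1.75e-09; adjusted p = 0.228 with an estimated correlation); matK fell from 887 ± 432 to 162 ± 63.8 FPKM. In the chloroplast-encoded NDH complex 8 of 12 genes fell, ndhI from 145 ± 137 to 36.0 ± 12.6 FPKM, and 4 did not pass. Relative to all genes, the list median was -1.25 (camera adjusted p = 1.5e-05; adjusted p = 0.258 with an estimated correlation). In the nuclear-encoded plastid transcription machinery 12 of 20 genes fell, 2 rose and 6 did not pass. Taken as a list, the relative median was -0.73 (camera adjusted p = 1.62e-05; adjusted p = 0.509 with an estimated correlation). Here the polymerase gene RPOTP fell from 9.45 ± 3.47 to 3.51 ± 0.558 FPKM, and the sigma factor SIG5 rose from 20.7 ± 10.4 to 67.7 ± 5.60.

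The photosynthesis lists were called as deposited but not after quantile normalization, though camera pointed downwards under both. Of 18 antenna genes 8 fell, LHCB2.3 from 1163 ± 219 to 642 ± 122 FPKM, 10 did not pass and 0 rose; the median change was -0.23 as deposited and 0.045 after quantile normalization (camera adjusted p = 0.000514 and 0.693, and adjusted p = 0.523 with an estimated correlation). LHCB1.4 (-0.81 ± 0.24, adjusted p = 0.00607) and LHCB4.1 (-0.40 ± 0.08, adjusted p = 0.000192) fell as deposited. After quantile normalization their changes of -0.50 and -0.14 did not pass (adjusted p = 0.134 and 0.202), and without the set term LHCB1.4 did not pass at the deposited change of -0.81 (adjusted p = 0.0531). Of 29 nuclear-encoded genes of the photosystems and electron transport 8 fell, FD2 from 1226 ± 163 to 624 ± 82.5 FPKM, 1 rose and 20 did not pass, with a median of -0.13 as deposited and 0.008 after quantile normalization (camera adjusted p = 4.25e-05 and 0.626, and adjusted p = 0.575 with an estimated correlation). Of 32 chloroplast-encoded genes of the photosystems and cytochrome complex 11 fell, 3 rose and 18 did not pass (median -0.19, camera adjusted p = 0.000678; after quantile normalization 0.691; adjusted p = 0.228 with an estimated correlation). In the Calvin-Benson cycle 9 of 17 genes fell, RBCS1A from 2523 ± 369 to 1578 ± 243 FPKM, 1 rose and 7 did not pass (median -0.32 as deposited and -0.16 after quantile normalization, camera adjusted p = 4.25e-05 and 0.208; adjusted p = 0.509 with an estimated correlation). Members of the LHCB1, RBCS and duplicated chloroplast genes share long stretches of sequence, so the split of reads between them is uncertain.

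Genes of recycling and of senescence control rose early, in leaves of 14 to 18 days. Of 29 autophagy genes 28 rose, 0 fell and 1 did not pass. For the whole list the relative median was 0.72 (camera adjusted p = 8.02e-06; adjusted p = 0.486 with an estimated correlation). ATG8A rose from 6.02 ± 1.43 to 21.5 ± 5.02 FPKM and the cargo receptor NBR1 from 42.8 ± 7.60 to 108 ± 12.8. All 13 measured genes of beta-oxidation and the glyoxylate cycle rose, PED1 from 47.9 ± 11.4 to 149 ± 22.1 FPKM. The list had a relative median of 0.72 (camera adjusted p = 0.00293; adjusted p = 0.523 with an estimated correlation). Of 20 NAC and WRKY regulators of senescence 16 rose, ORE1 from 0.210 ± 0.200 to 13.9 ± 7.64 FPKM (3.53 ± 0.25) and NAP from 7.35 ± 4.25 to 37.6 ± 11.1 (2.42 ± 0.35). In that list 2 did not pass and 2 fell, WRKY53 from 24.0 ± 12.4 to 8.97 ± 4.74 FPKM. The relative median of the list was 0.91 (camera adjusted p = 0.00973; adjusted p = 0.523 with an estimated correlation). In the salicylic acid and defence list 11 of 15 genes rose, PR1 from 0.0475 ± 0.0565 to 9.88 ± 9.07 FPKM and PAD4 from 2.98 ± 1.53 to 11.1 ± 0.979, and 4 did not pass. This gave the list a relative median of 0.59 (camera adjusted p = 0.0419; adjusted p = 0.595 with an estimated correlation). Of 20 abscisic acid genes 13 rose, NCED3 from 6.52 ± 2.73 to 26.5 ± 6.01 FPKM, 1 fell and 6 did not pass. As a group these genes had a relative median of 0.57 (camera adjusted p = 0.0347; adjusted p = 0.523 with an estimated correlation).

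Some lists held many risen genes without passing camera. Of 10 genes of chlorophyll breakdown 8 rose, PPH from 12.8 ± 2.05 to 53.6 ± 11.8 FPKM and PAO from 25.2 ± 4.89 to 63.1 ± 18.0, 1 fell and 1 did not pass. The members had a relative median of 0.91 (adjusted p = 0.0547; 0.0364 after quantile normalization). Of 16 genes of nitrogen remobilization 10 rose, DUR3 from 0.619 ± 0.511 to 21 ± 7.52 FPKM and GLN1;1 from 23.8 ± 9.07 to 103 ± 32.9, 1 fell and 5 did not pass. Relative to all genes, the list median was 0.64 (adjusted p = 0.0993; 0.0313 after quantile normalization). Among 15 senescence-associated markers 9 rose, SEN1 from 10.4 ± 5.47 to 129 ± 21.4 FPKM, 1 fell and 5 did not pass. Taken as a list, the relative median was 0.41 (adjusted p = 0.097; 0.0497 with nuclear genes rescaled, 0.0198 after quantile normalization and 0.0438 without day 4). SAG12, the cysteine protease gene used as a senescence marker, was not among them, at 0.0318 ± 0.0531 and 0.739 ± 1.33 FPKM (0.49 ± 0.25, adjusted p = 0.088), but passed with a pseudocount of 0.1 (adjusted p = 0.0142), with nuclear genes rescaled (0.0263) and with narrower stages (0.0314). Of 12 vacuolar and cell-death proteases 7 rose, GAMMA-VPE from 25.2 ± 10.2 to 302 ± 108 FPKM, 2 did not pass and 3 fell, XCP1, a protease of developing xylem, from 10.3 ± 3.17 to 1.4 ± 0.763. For the whole list the relative median was 0.81 (adjusted p = 0.57). In the anthocyanin list 3 of 11 genes rose, 2 fell, CHS from 46.7 ± 10.7 to 8.91 ± 3.55 FPKM, and 6 did not pass, with a median of 0.09, a mean of -0.07 and a camera test pointing downwards (adjusted p = 0.186). Of 14 mitochondria-encoded respiration genes 6 rose, 1 fell and 7 did not pass (relative median -0.06, adjusted p = 0.95), and of 10 mitochondria-encoded genes of gene expression and cytochrome maturation 7 rose and 3 did not pass. The list had a relative median of 0.10 (adjusted p = 0.48). Adjusted over the list alone, 7 antenna genes and 10 chloroplast-encoded photosystem genes fell, 2 anthocyanin genes rose and 0 mitochondria-encoded respiration genes fell; the other counts equal those over all genes tested. None of the 18 lists called in this comparison held its call with an estimated correlation.

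**Figure D1:**
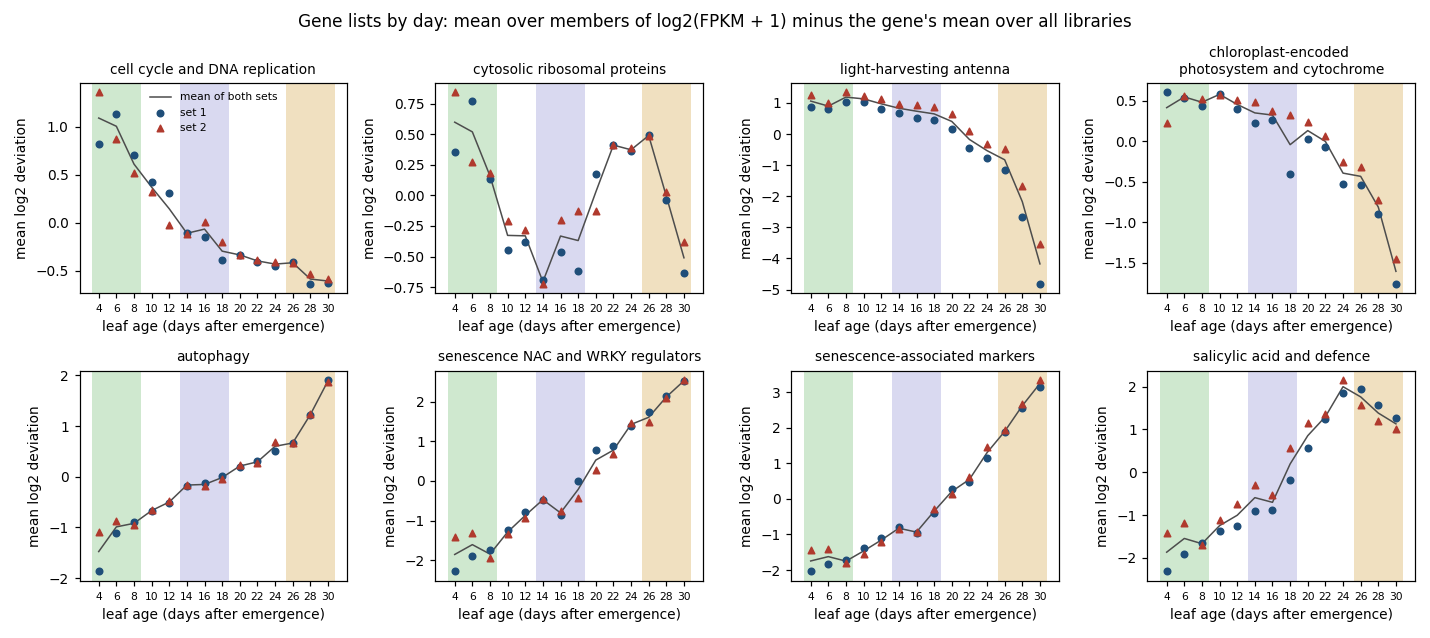
Mean over the members of 8 gene lists of log2(FPKM + 1) minus each gene's mean over all libraries, against leaf age in days; circles are set 1, triangles set 2, lines the mean of both sets, and shaded bands the young, mature and old stages. Cytosolic ribosomal proteins stood at -0.69 and -0.72 at day 14, at 0.49 and 0.49 at day 26 and at -0.64 and -0.38 at day 30 (sets 1 and 2).

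The second comparison asked how transcripts differ between mature and senescing leaves. SAG12 (AT5G45890) showed the largest rise, from 0.739 ± 1.33 to 1531 ± 1139 FPKM (9.44 ± 0.25, adjusted p = 5.91e-16, limma). The nitrilase gene NIT2 (AT3G44300) rose from 1.04 ± 1.21 to 467 ± 330 FPKM (7.69 ± 0.16, adjusted p = 4.37e-17) and PES1 (AT1G54570), which esterifies phytol, from 1.95 ± 0.474 to 327 ± 235 (6.30 ± 0.14, adjusted p = 1.35e-16). CCD8 (AT4G32810), a carotenoid cleavage enzyme of strigolactone synthesis, rose from 0.0717 ± 0.123 to 111 ± 66.4 FPKM (6.38 ± 0.13, adjusted p = 4.37e-17). KTI1 (AT1G73260), CYP76C2 (AT2G45570), DOX1 (AT3G01420), GLYI7 (AT1G80160), AT5G39520 and AT1G62760 completed the 10 largest rises, with changes of 6.04 to 6.60. Of the 10 largest falls 3 were antenna genes, LHCB2.3 (AT3G27690) from 642 ± 122 to 14.5 ± 22.3 FPKM (-6.30 ± 0.18, adjusted p = 2.42e-15), LHCB1.4 (AT2G34430) from 1106 ± 270 to 54.4 ± 67.9 (-5.23 ± 0.24, adjusted p = 1.05e-12) and Lhca6 (AT1G19150) from 87.5 ± 21.6 to 2.61 ± 4.25 (-5.18 ± 0.19, adjusted p = 3.72e-14). CA1 (AT3G01500), the main carbonic anhydrase of the leaf, fell from 753 ± 165 to 27.6 ± 39.4 FPKM (-5.74 ± 0.20, adjusted p = 2.37e-14) and the myrosinase gene TGG2 (AT5G25980) from 67.9 ± 33.6 to 0.773 ± 0.570 (-5.16 ± 0.19, adjusted p = 3.87e-14). The expansin EXPA8 (AT2G40610), the aldolase FBA5 (AT4G26530), ELP (AT1G12090), DGR2 (AT5G25460) and AT1G66100 were the others, with changes of -6.60 to -5.18.

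Between these stages 8807 genes were higher and 4943 lower, and the median change of all tested genes was 0.26. Higher calls were 64.1% of all calls as deposited and 51.9% after quantile normalization (6979 higher, 6474 lower). Ribosomal RNA genes took 0.104 to 0.421% of the FPKM of the old libraries and 0.0513 to 0.0802% of that of the mature ones, with no overlap.

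Photosynthesis genes fell together. All 18 antenna genes fell (relative median -3.15), as did all 29 nuclear-encoded genes of the photosystems and electron transport (-2.57), all 17 genes of the Calvin-Benson cycle (-2.81), all 17 of chlorophyll synthesis (-2.61) and all 12 of the chloroplast-encoded NDH complex (-2.38). LHCB1.1 fell from 1449 ± 216 to 199 ± 226 FPKM (-3.84 ± 0.18), PSBQ1 from 469 ± 77.1 to 65.3 ± 56.5 (-3.41 ± 0.15), RCA, which activates Rubisco, from 1740 ± 191 to 654 ± 339 (-1.61 ± 0.09) and CHLH, a subunit of magnesium chelatase, from 455 ± 66.6 to 56.5 ± 49.4 (-3.47 ± 0.12). The camera adjusted p-values of these 5 lists were 5.8e-14, 4.2e-20, 7.14e-14, 2.45e-11 and 1.84e-07; with an estimated correlation the adjusted p-values were 0.144, 0.153, 0.144, 0.144 and 0.144. Of 32 chloroplast-encoded genes of the photosystems and cytochrome complex 23 fell, rbcL from 8407 ± 1356 to 2989 ± 1540 FPKM and psaA from 2752 ± 274 to 916 ± 412, 1 rose and 8 did not pass (relative median -1.45). This was the only list called with an estimated correlation (adjusted p = 1.64e-09 with the preset and 0.0118 with the estimated one). The most abundant of these transcripts, psbA, fell from 16325 ± 1612 to 11667 ± 1976 FPKM (-0.50 ± 0.11, adjusted p = 0.000733). After quantile normalization its change was 0. That method gives a transcript of the same rank in every library the same value, so this decides nothing about the fall. Without the filter on low genes the same change of -0.50 did not pass (adjusted p = 0.239). Of 27 chloroplast-encoded genes of gene expression 25 fell, or 26 adjusted over the list alone, and 2 did not pass. The relative median of the list was -1.88 (camera adjusted p = 1.81e-10; adjusted p = 0.144 with an estimated correlation). In the plastid transcription machinery 16 of 20 genes fell, SIG4 from 16.1 ± 2.68 to 2.31 ± 2.16 FPKM, and 4 did not pass. This gave the list a relative median of -1.05 (camera adjusted p = 1.21e-06; adjusted p = 0.345 with an estimated correlation).

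Growth genes were lower still in old leaves. Of 13 cell wall genes 12 fell, EXPA11 from 22.1 ± 8.37 to 0.392 ± 0.268 FPKM and the cellulose synthase CESA3 from 120 ± 6.51 to 56.2 ± 22.9, and 1 did not pass. As a group these genes had a relative median of -2.31 (camera adjusted p = 8.74e-08; adjusted p = 0.169 with an estimated correlation). Of 19 cell cycle genes 12 fell, CDC6 from 3.05 ± 0.876 to 0.195 ± 0.219 FPKM, 1 rose and 6 did not pass. The members had a relative median of -0.66 (camera adjusted p = 0.00315; adjusted p = 0.485 with an estimated correlation). Cytosolic ribosomal protein genes did not follow: 10 of 17 rose, RPL10C from 46.2 ± 6.04 to 208 ± 88.0 FPKM, and 7 did not pass. Relative to all genes, the list median was 0.11 (camera adjusted p = 0.156). Among vascular markers 6 of 8 fell, SUC2 from 197 ± 20.4 to 107 ± 19.5 FPKM, and 2 rose, the sucrose exporter SWEET12 from 4.49 ± 1.19 to 21.4 ± 9.11. Taken as a list, the relative median was -0.87 (camera adjusted p = 0.0696). Of 6 stomatal genes 3 fell, GC1 from 11.1 ± 4.48 to 1.53 ± 0.772 FPKM, 2 rose and 1 did not pass. For the whole list the relative median was -0.45 (camera adjusted p = 0.543). Of the 3 measured meristem and flower genes PI rose, from 0.0484 ± 0.0456 to 0.901 ± 0.433 FPKM, 1 fell and 1 did not pass, with a median of -0.13, a mean of 0.12 and a camera test pointing downwards (adjusted p = 0.806).

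Regulators and executors of senescence rose. Of 20 NAC and WRKY genes 19 rose and 1 did not pass (relative median 2.24, camera adjusted p = 5.18e-06; adjusted p = 0.232 with an estimated correlation), WRKY75 from 0.321 ± 0.285 to 47.7 ± 30.1 FPKM (4.98 ± 0.09), NAC055 from 4.85 ± 2.52 to 235 ± 227 (4.81 ± 0.22) and ORE1 from 13.9 ± 7.64 to 103 ± 45.3 (2.77 ± 0.25). Of 15 senescence-associated markers 14 rose and 1 did not pass (relative median 2.27, camera adjusted p = 8.17e-06; adjusted p = 0.135 with an estimated correlation), among them BFN1, a nuclease, from 0.343 ± 0.0994 to 107 ± 127 FPKM (5.21 ± 0.18). Of 29 autophagy genes 27 rose, ATG7 from 4.50 ± 0.271 to 67.4 ± 59.4 FPKM and ATG8A from 21.5 ± 5.02 to 157 ± 80.0, and 2 did not pass. The list had a relative median of 1.01 (camera adjusted p = 1.51e-06; adjusted p = 0.345 with an estimated correlation). Of 12 proteases 10 rose, CEP1 from 0.133 ± 0.103 to 38.8 ± 32.7 FPKM and MC9 from 1.16 ± 0.358 to 59.0 ± 62.9, and 2 fell. The relative median of the list was 1.16 (camera adjusted p = 0.0265; adjusted p = 0.348 with an estimated correlation). In beta-oxidation 11 of 13 genes rose, ACX2 from 21.3 ± 1.05 to 138 ± 78.4 FPKM, 1 did not pass and KAT5 fell from 31.1 ± 3.45 to 19.4 ± 9.39. This gave the list a relative median of 1.01 (camera adjusted p = 0.00216; adjusted p = 0.419 with an estimated correlation). All 15 salicylic acid and defence genes rose, PBS3 from 5.83 ± 3.97 to 50.7 ± 13 FPKM. As a group these genes had a relative median of 1.42 (camera adjusted p = 0.00188; adjusted p = 0.395 with an estimated correlation). Of 20 abscisic acid genes 15 rose, HAI2 from 2.00 ± 0.973 to 20.6 ± 14.3 FPKM, 2 fell and 3 did not pass. The members had a relative median of 0.58 (camera adjusted p = 0.0046; adjusted p = 0.362 with an estimated correlation).

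Chlorophyll breakdown genes moved both ways. Of 10 genes 7 rose, NYE1 from 16.5 ± 3.31 to 342 ± 252 FPKM (3.90 ± 0.12) and NYC1 from 49.9 ± 8.35 to 573 ± 347 (3.24 ± 0.14), and 3 fell, the chlorophyllase CLH1 from 88.0 ± 17.1 to 28.7 ± 31 (-2.53 ± 0.26), and the list did not pass. Relative to all genes, the list median was 1.05 (camera adjusted p = 0.13). In nitrogen remobilization 12 of 16 genes rose, the cytosolic glutamine synthetase GLN1;1 from 103 ± 32.9 to 745 ± 259 FPKM and GDH2 from 9.95 ± 1.87 to 169 ± 123, 1 did not pass and 3 fell, the plastid glutamine synthetase GLN2 from 367 ± 43.4 to 96.8 ± 60.7. Taken as a list, the relative median was 1.56 (camera adjusted p = 0.112; 0.0208 after quantile normalization). Of 11 anthocyanin genes 8 rose, DFR from 0.226 ± 0.313 to 97.2 ± 86.6 FPKM (5.75 ± 0.53) and the regulator PAP2 from 0.0681 ± 0.126 to 32.8 ± 23.4 (4.48 ± 0.39), 2 did not pass and FLS1 fell. For the whole list the relative median was 2.74 (camera adjusted p = 0.0827; 0.0421 after quantile normalization). Of 6 heat shock genes, the sign of handling stress, 5 rose, HSP70 from 4.45 ± 2.3 to 44.0 ± 16.5 FPKM, and 1 did not pass. The list had a relative median of 0.91 (camera adjusted p = 0.0348; 0.0698 without day 4; adjusted p = 0.395 with an estimated correlation). Of 9 clock genes 5 rose, TOC1 from 5.72 ± 1.09 to 14.8 ± 1.44 FPKM, 2 fell and 2 did not pass. The relative median of the list was 0.33 (camera adjusted p = 0.502). Among mitochondria-encoded genes 5 of 14 respiration genes rose, cox3 from 220 ± 16.6 to 365 ± 30.1 FPKM, and 9 did not pass (relative median -0.01, camera adjusted p = 0.543), while in gene expression and cytochrome maturation 3 of 10 rose, 1 fell and 6 did not pass. This gave the list a relative median of -0.13 (camera adjusted p = 0.77), and its own median was 0.14 as deposited and -0.01 after quantile normalization. Apart from the 27 plastid genes named above, counts adjusted over the list alone equal those over all genes tested.

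The share of chloroplast-encoded transcripts fell with age, while a rise of the mitochondria-encoded share depended on how it was measured. Chloroplast-encoded genes took 19.9 ± 1.99% of the summed FPKM in young leaves, 16.7 ± 0.949% in mature and 7.93 ± 2.39% in old leaves (SD, n = 6). Both falls, of -0.25 and -1.13 on the log2 scale, reached the smallest p of a 2-sided exact permutation test within sets (p = 0.005 each). Mitochondria-encoded genes took 1.14 ± 0.280%, 1.33 ± 0.0925% and 1.62 ± 0.294%. The first step (0.24, exact permutation p = 0.095) did not pass, but did with day 4 left out (0.35, p = 0.01), without its set 1 library (0.36) and as a median change of the genes (0.31, p = 0.005). The second (0.27, p = 0.03) did not pass as a share of the nuclear sum (0.13, p = 0.23), as a median change of the genes (0.22, p = 0.125), or without the set 2 library of day 14 (p = 0.065), 16 (p = 0.08) or 18 (p = 0.055) or the set 1 library of day 26 (p = 0.08) or 28 (p = 0.08), all by exact permutation.

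**Figure D2:**
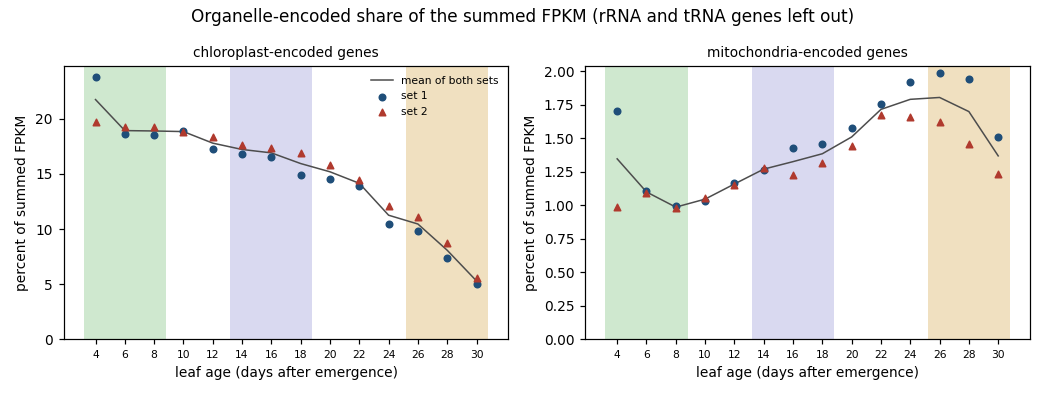
Percent of summed FPKM from chloroplast-encoded (left) and mitochondria-encoded genes (right) against leaf age in days, with rRNA and tRNA genes left out; circles are set 1, triangles set 2, lines the mean of both sets, and shaded bands the young, mature and old stages. The chloroplast share ended at 5.0% and 5.56% on day 30, and the mitochondrial share stood at 1.99% and 1.62% on day 26 and at 1.51% and 1.23% on day 30 (sets 1 and 2).

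Small RNA reads shifted from short to longer lengths as leaves aged. Reads of 21 nt, the length of most microRNAs, made up 22.8 ± 4.77% of listed reads in young, 18.9 ± 1.62% in mature and 9.13 ± 2.43% in old leaves (SD, n = 4). Reads of 24 nt, the length of siRNAs that guide DNA methylation, made up 3.87 ± 0.558%, 3.87 ± 0.348% and 2.09 ± 0.337%. Reads of 29 to 33 nt, a class chosen after its share was seen, made up 10.5 ± 6.90%, 24.7 ± 5.79% and 61.3 ± 5.8%. From mature to old leaves the log2 share of 21 nt reads fell by 1.09 and that of 24 nt reads by 0.90, and that of 29 to 33 nt reads rose by 1.34, each with p = 0.0286, the smallest that a 2-sided exact permutation test of 4 against 4 libraries can give. From young to mature leaves the changes were -0.25 for 21 nt (exact p = 0.229), 0.01 for 24 nt (exact p = 0.943) and 1.49 for 29 to 33 nt (exact p = 0.0286). The last did not pass without day 4 (exact p = 0.0667), without the 10 most abundant sequences (exact p = 0.0857), without the day 12 library of set 1 (exact p = 0.0857) or without that of set 2 or either day 16 library (exact p = 0.114 each). Permuted within sets, where no exact p can be under 0.0556, none of these changes passed. As a share of 20 to 24 nt reads, which leaves out the longer reads, 21 nt reads rose from mature to old leaves by 0.19 and 24 nt reads by 0.39 (exact p = 0.0286 each), opposite to their share of all listed reads.

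**Figure D3:**
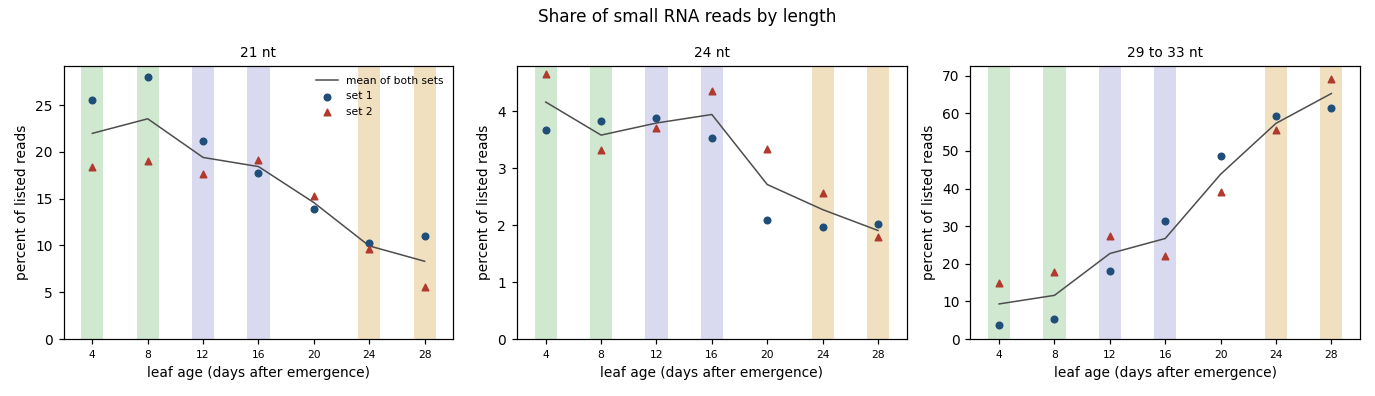
Percent of listed small RNA reads of 21 nt, 24 nt and 29 to 33 nt against leaf age in days; circles are set 1, triangles set 2, lines the mean of both sets, and shaded bands the young, mature and old stages. On day 4 reads of 29 to 33 nt were 3.84% in set 1 and 14.8% in set 2, and on day 28 they were 61.3% and 69.2%.

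Single small RNA sequences were compared by their counts with edgeR, and their orientation and origin were not determined here. Of 46841 sequences tested, 4667 changed over the 7 days. In old against mature leaves 4212 were higher and 1761 lower. Of the 8013 sequences of 29 to 33 nt, 1134 were higher and 128 lower, and of the 5296 of 34 to 48 nt, 978 were higher and 0 lower (edgeR; all tested lengths together had 13790 sequences at an unadjusted p under 0.05). Among 21 nt sequences 204 were higher and 236 lower. The largest rise by the fixed rule was that of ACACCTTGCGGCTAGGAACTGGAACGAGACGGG, from 0.0280 ± 0.0560 to 31.6 ± 17.5 CPM (counts scaled to library size; edgeR adjusted p = 0.000295), and the largest fall that of GGATAGCCAAGGAGACTGCC, from 21.8 ± 15.4 to 0.0844 ± 0.169 CPM (edgeR adjusted p = 0.000514). GATAGCCAAGGAGACTGCC, 1 nt shorter, fell from 20.5 ± 14.5 to 0.208 ± 0.320 CPM (edgeR adjusted p = 0.00202). No fold is given where a stage held fewer than 10 counts. Without 1 library the higher count was 1691 and 2113 (day 12, sets 1 and 2), 2505 and 1429 (day 16), 1241 (day 24, set 1) or 1357 (day 28, set 2). The lower count was then 400 and 544 (day 12), 716 and 334 (day 16), 265 and 786 (day 24) or 876 and 409 (day 28, sets 1 and 2), and the count over the 7 days was 2899 without day 24 of set 1 and 2221 without day 28 of set 2.

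In mature against young leaves 1016 sequences were higher and 146 lower, but 0 passed in either direction without day 4 (edgeR; 3956 had an unadjusted p under 0.05, and DESeq2 on all days called 1267 higher and 329 lower). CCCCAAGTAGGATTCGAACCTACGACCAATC, of 31 nt, had 0 counts in young libraries and 12.1 ± 14.1 CPM in mature ones, and GGCAGGGCTAGTGACTGGAGTGA went from 0.247 ± 0.240 to 37.4 ± 38.4 CPM (edgeR adjusted p = 0.00297 each). GGAGAACATGATCGTTTGGTACGA fell from 8.05 ± 5.02 to 0.494 ± 0.414 CPM (-4.14 ± 0.70, edgeR adjusted p = 0.0119), and TTGGCATTCTGTCCACCTCCT, which holds the fixed miR394 sequence, from 1.92 ± 1.7 to 0.184 ± 0.224 CPM (edgeR adjusted p = 0.0196). Without day 4, which leaves 2 young libraries, the direction of all 4 was kept and their calls were lost (adjusted p = 0.131, 0.168, 0.292 and 0.292); the change of GGAGAACATGATCGTTTGGTACGA was then -3.93. Without 1 library the higher count was 536 and 475 (day 4, sets 1 and 2), 606 (day 8, set 1), 187 (day 12, set 2), 303 (day 16, set 1), 532 and 523 (day 24) or 657 and 670 (day 28, sets 1 and 2). The lower count was then 24 and 260 (day 4), 50 (day 8, set 2), 16 and 11 (day 12), 10 and 31 (day 16) or 93 and 93 (day 24, sets 1 and 2).

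Of 28 microRNA families found by their mature sequence, 13 changed over the 7 days (edgeR; 26 without the day 4 library of set 2). Each family was counted by 1 mature sequence, so members with another sequence are left out. In mature against young leaves 7 families were lower and 1 higher. miR165, which represses class III homeodomain genes, fell from 21253 ± 7693 to 8542 ± 2586 CPM (-1.29 ± 0.22, adjusted p = 0.00246) and miR158 from 27894 ± 11754 to 13097 ± 3823 (-1.04 ± 0.21, adjusted p = 0.00586). miR171 fell from 195 ± 322 to 10.3 ± 3.46 CPM (-3.24 ± 0.72, adjusted p = 0.00721), miR319, which represses TCP growth regulators, from 102 ± 120 to 16.4 ± 8.10 (-2.20 ± 0.57, adjusted p = 0.0144), miR394 from 268 ± 470 to 13.9 ± 3.56 (-2.95 ± 0.77, adjusted p = 0.0144) and miR399 from 12.2 ± 5.75 to 1.92 ± 0.886 (-2.47 ± 0.68, adjusted p = 0.0146). miR169 fell from 53.6 ± 102 to 1.62 ± 1.02 CPM (adjusted p = 0.0391) and miR398 rose from 0.313 ± 0.319 to 1.26 ± 0.489 (adjusted p = 0.0145), and both calls were lost without day 4. Counts were low, with 11 in young and 52 in mature libraries for miR398. In mature libraries miR169 held 58 and miR399 81. The size of 4 of these falls rests on the day 4 library of set 1, at 678 CPM for miR171, 973 for miR394, 279 for miR319 and 207 for miR169. The other young libraries held at most 53.2, 50.7, 72.6 and 4.14 CPM of these. Without that library the changes were -1.73 for miR171, -1.25 for miR394, -1.59 for miR319 and -0.89 for miR169. Without the day 4 library of set 2 they were -3.58 for miR394 and -3.75 for miR169, and miR169 changed by -2.20 and -2.38 without day 8 of set 2 and day 12 of set 1 and by -4.07 without day 12 of set 2. Leaving out any 1 library kept the calls of miR158 and miR165 (edgeR), but miR158 lost its call without the set term (adjusted p = 0.0948). miR169 lost its call without the set 1 library of day 4 (adjusted p = 0.138), 12 (0.208) or 16 (0.133) or the set 2 library of day 8 (0.356) or 16 (0.132). Without the day 12 library of set 1 the changes were -2.94 for miR171, -1.91 for miR319, -2.58 for miR394, 2.68 for miR398 and -2.12 for miR399. In the same order the adjusted p (edgeR) was 0.063, 0.0833, 0.0955, 0.0515 and 0.0955. Without the day 16 library of set 1 it was 0.05 for miR171, 0.0896 for miR319, 0.0896 for miR394 and 0.101 for miR399, and without the day 8 library of set 2 it was 0.0796 for miR319, 0.0724 for miR394, 0.0796 for miR398 and 0.0642 for miR399.

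In old against mature leaves 5 families were lower and 2 higher. miR164, which represses ORE1, fell from 9.34 ± 4.02 to 1.58 ± 1.89 CPM (-3.12 ± 0.64, adjusted p = 0.00403, edgeR) and miR165 from 8542 ± 2586 to 2251 ± 1319 (-2.07 ± 0.23, adjusted p = 3.27e-05). miR164 held 333 counts in mature and 22 in old libraries. miR160 fell from 645 ± 212 to 269 ± 206 CPM (-1.47 ± 0.38, adjusted p = 0.0163), miR319 from 16.4 ± 8.10 to 4.88 ± 5.59 (-2.13 ± 0.60, adjusted p = 0.0194) and miR158 from 13097 ± 3823 to 8355 ± 3718 (-0.69 ± 0.21, adjusted p = 0.0273). miR827, which acts in phosphate homeostasis, rose from 73.2 ± 31.6 to 484 ± 260 CPM (2.66 ± 0.39, adjusted p = 0.000293), and the copper-responsive miR408 from 98.6 ± 20.0 to 342 ± 178 (1.61 ± 0.45, adjusted p = 0.0194). With reads of 18 to 28 nt alone, a setting chosen after the data were seen, miR158, miR160 and miR319 lost their call in this comparison. miR158 also lost it with DESeq2 size factors in edgeR (adjusted p = 0.119) and with DESeq2 (adjusted p = 0.296). Without the set term in edgeR the adjusted p was 0.576 for miR158, 0.204 for miR160, 0.164 for miR319 and 0.164 for miR408. miR166, the most abundant family, was not called in either comparison (50971 ± 26086, 58562 ± 7588 and 65537 ± 27374 CPM). These CPM carry the TMM factors, and the summed counts of miR166 were 2144795, 2233914 and 1000169 in young, mature and old libraries. Leaving out any 1 library kept the calls of miR164, miR165 and miR827 (edgeR). miR158 lost its call without the set 1 library of day 8 (adjusted p = 0.0637), 16 (0.103), 20 (0.0756) or 28 (0.202) or the set 2 library of day 8 (0.0616), 12 (0.0973), 16 (0.0929), 24 (0.153) or 28 (0.0686). For miR160 the adjusted p was 0.0635 without the set 2 library of day 12, 0.0555 without that of day 16, 0.0914 without that of day 24, and 0.0651 and 0.087 without the set 1 libraries of days 16 and 28. For miR319 these values were 0.0841, 0.0652, 0.11, 0.0651 and 0.13. miR408 lost its call without the set 1 library of day 12 (0.0629) or 16 (0.107) or the set 2 library of day 16 (0.0652), 24 (0.0564) or 28 (0.0504).

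**Figure D4:**
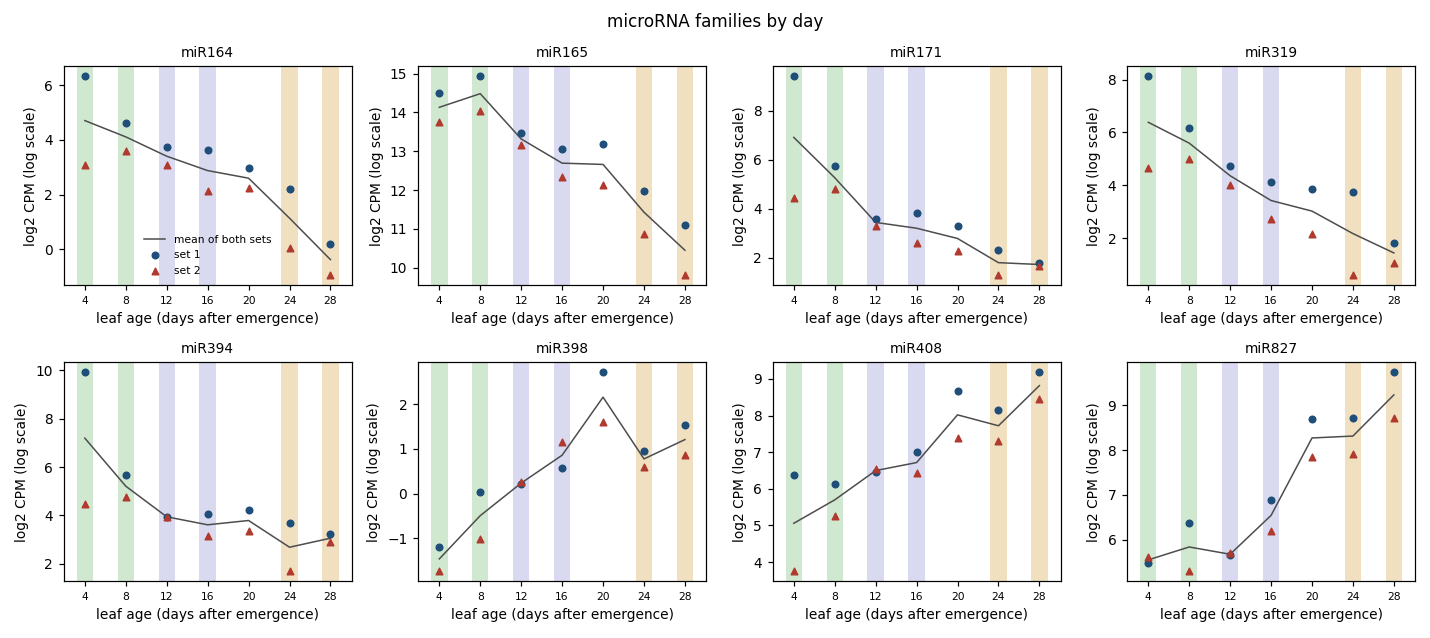
Level of 8 microRNA families as log2 CPM (log scale) against leaf age in days; circles are set 1, triangles set 2, lines the mean of both sets, and shaded bands the young, mature and old stages. miR827 and miR408 rose and miR164, miR165 and miR319 fell from mature to old leaves by the test across 4 libraries per stage.

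Levels of microRNAs and of target transcripts were set against each other over 14 pairs of libraries of the same day and set, each centred on its set. Of 45 pairs fixed beforehand, 32 had a negative Pearson correlation (19 in both sets), 11 of them past an adjusted p of 0.05, and 2 were positive past it. miR164 and ORE1 had r = -0.884 (permutation p = 0.0001, adjusted p = 0.00108) and rho = -0.916 (permutation p = 4e-05), with r = -0.924 in set 1, -0.837 in set 2 and -0.840 without the 2 farthest pairs. miR171 and SCL27 had r = -0.913 (permutation p = 4e-05, adjusted p = 0.0009) and rho = -0.899 (permutation p = 4e-05), with -0.955 and -0.818 in the sets and -0.798 without the 2 farthest. miR399 and PHO2, a regulator of phosphate uptake, had r = -0.895 (permutation p = 8e-05, adjusted p = 0.00108), rho = -0.833 (permutation p = 0.00091), -0.909 and -0.898 in the sets and -0.810 without the 2 farthest. The others were miR164 with NAC1 and NAC100, miR394 with LCR, miR398 with CSD2 and CCS, miR160 with ARF10 and ARF16 and miR319 with TCP2. Some of these families rest on low counts. Old libraries held 15 counts of miR399 and 22 of miR164, and young libraries 11 of miR398. The positive pairs were miR827 and NLA (r = 0.903, permutation p = 1e-05, the smallest that 100000 permutations give, adjusted p = 0.00045; rho = 0.873, permutation p = 0.00015; 0.891 and 0.940 in the sets and 0.843 without the 2 farthest) and miR319 and TCP4 (r = 0.818, permutation p = 0.00023, adjusted p = 0.00148; rho = 0.921, permutation p = 2e-05; 0.775 and 0.917 in the sets and 0.908 without the 2 farthest). Without the 2 farthest pairs 7 negative pairs passed, and miR319 and TCP2 did not pass without day 4 (r = -0.439, adjusted p = 0.292). The other negative pairs still passed without day 4, but more positive pairs then passed (permutation, adjusted p of 0.0116 to 0.0476). These were miR156 with SPL2 (r = 0.789), miR167 with ARF8 (0.729), miR171 with SCL22 (0.821), miR393 with TIR1 (0.773), miR395 with APS4 (0.779) and miR396 with GRF2 (0.811). The excess of negative pairs was thus smaller without day 4. Most genes change with age, and in the median pair 46.8% of all tested genes had a lower r with the microRNA than its target did. Among the 11 negative pairs that passed, this percentage ran from 1.398 (miR399 and PHO2) to 50.8 (miR319 and TCP2). It was 24.2 for miR164 and ORE1 and 17.7 for miR171 and SCL27. A small permutation p therefore does not show that a correlation is specific to the target.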

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

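Of the tests of the day 4 library below, that of its chloroplast-encoded share was chosen after the result was seen and the others before. For each library value per stage, the gap between the farthest library and its nearest neighbour was divided by the range of the stage, and 25 of 191 groups exceeded Dixon's 95% limit, where chance alone gives about 1 in 20, or 9.55.

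The day 4 total RNA library of set 1 was the farthest young library in summed FPKM (gap ratio 0.775), genes at 1 FPKM or above (0.769), chloroplast-encoded share (0.789), mitochondria-encoded share (0.826) and ribosomal RNA share (0.942). The day 4 small RNA library of set 1 was the farthest in miR395, at 2.3 log2 CPM against -1.73 to -1.28 in the other young libraries (0.888).

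The values argue against 2 technical readings of the day 4 library and do not decide a biological one. For an earlier leaf stage, its difference from set 2 was predicted to correlate positively with the difference between days 6 and 10. That correlation was -0.0673 over 18239 genes. From day 6 to day 8 only 2 genes changed and from day 8 to day 10 only 25 (limma). The reference difference thus holds little change, and the correlation decides nothing. A single scale factor on its FPKM leaves shares as they are and is argued against by its chloroplast-encoded share of 23.8%, against 18.6 to 19.7% in the other young libraries; the correlation of 0.936 with set 2 after quantile normalization decides nothing, since a correlation hardly depends on scale. Fewer reads are argued against by a correlation of 0.908 in the 4560 genes with the highest mean, where other days have 0.957 to 0.989. A difference in how its RNA was prepared was not tested and stays open, as do an earlier leaf stage and a real difference between the plants of the sets.

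The day 18 library of set 1 was the farthest mature library in AT1G34060 (gap ratio 0.711), AT5G18130 (0.761), AT2G10940 (0.642), LHCB2.3 (0.717), EXPA8 (0.658), LHCB1.4 (0.692), DGR2 (0.718) and Lhca6 (0.650). It was lowest in AT2G10940, LHCB2.3, EXPA8, LHCB1.4, DGR2 and Lhca6 and highest in the other 2. These genes were picked for their change with age, and many of their values in a library move together, so the 8 groups are not independent. The day 18 library of set 2 was the farthest in KTI1 (0.658), CYP76C2 (0.706) and CCD8 (0.758), the day 14 library of set 1 in AT3G16670 (0.671) and GPAT3 (0.905), and the day 16 library of set 2 in AT5G45670 (0.641). Among young libraries CAX3 was highest at day 6 of set 2 (0.736), and among old ones EXPA8 at day 26 of set 2 (0.716).

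In the small RNA the day 12 library of set 1 held the fewest reads of the mature stage, 4905408 against 8085840 to 8709996 (0.836). miR394 was lowest in the day 16 library of set 2, 3.15 log2 CPM against 3.93 to 4.07 (0.845), and miR393 highest in the day 24 library of set 1, 5.03 against 3.20 to 3.48 (0.847). No explanation was tested for these.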

How the results depend on the processing

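Leaving out day 4, reads of 18 to 28 nt alone, shares of 20 to 24 nt reads or of the nuclear sum, permutation of read lengths within sets and leaving out the 10 most abundant sequences were chosen after the data were seen. The cause of a change was not tested.

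Quantile normalization raised the genes lower in mature than young leaves from 3049 to 5390. With an estimated correlation 0 lists were called in mature against young leaves (limma camera; 18 with the preset correlation) and 1 in old against mature leaves. With set 1 alone, 3361 genes were higher and 888 lower in mature than young leaves and 3851 higher and 2440 lower in old than mature leaves; with set 2 alone the first were 3916 and 1474, and 3055 were lower in old leaves. DESeq2 gave 7335 small RNA sequences changing over the days and 329 lower in mature than young leaves, and reads of 18 to 28 nt alone gave 426 of the latter. Without day 4, 3100 sequences changed over the days and in mature against young leaves 0 were higher and 0 lower (edgeR; 3956 at an unadjusted p under 0.05).

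The mitochondria-encoded share rose from young to mature leaves by 0.307 as a median of the genes (exact permutation p = 0.005) and by 0.347 without day 4 (p = 0.01), on the log2 scale. From mature to old leaves it did not pass as a median of the genes (0.216, exact permutation p = 0.125) or of the nuclear sum (0.134, p = 0.23). As a share of 20 to 24 nt reads, 21 nt reads changed by 0.0409 from young to mature (exact p = 0.4) and by 0.188 from mature to old leaves (exact p = 0.0286), and 24 nt reads by 0.385 (exact p = 0.0286), against the direction of the main shares. The change of 24 nt reads from young to mature leaves was -0.0876 without microRNA sequences (exact p = 0.486) and -0.0292 without the 10 most abundant sequences (exact p = 0.8). Within sets the changes of -1.09 (21 nt), -0.897 (24 nt) and 1.34 (29 to 33 nt) from mature to old leaves, and of 1.49 (29 to 33 nt) from young to mature leaves, have an exact p of 0.0556, the smallest such a test can give. Without the 2 farthest library pairs 7 microRNA and target pairs passed in the negative direction.

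The 2 sets were fitted as blocks, but their differences from day to day are not shown to be shared: over 91 pairs of days the correlations of set differences ran from -0.146 to 0.65 with a median of 0.226 in the total RNA, 25 of them under 0.1, and over 21 pairs from -0.322 to 0.559 with a median of 0.0945 in the small RNA. Without the block 70 sequences were lower in mature than young and 1173 lower in old than mature leaves, and 755 and 3845 higher; 9085 and 2904 genes were higher and lower in mature leaves and 8609 and 4823 in old leaves; 11 families changed over the days, and 5 of 15 family calls and 1 of 191 values of named genes lost their call.

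With each library left out in turn, 16057 to 17568 genes changed over the days; 8648 to 10945 were higher and 2749 to 3931 lower in mature leaves, and 8310 to 9513 higher and 4633 to 5392 lower in old leaves. The interval with the most changes held 3016 to 10891, and 15 to 19 and 19 to 20 lists were called. For small RNA sequences the ranges were 2221 to 5626 over the days, 187 to 936 and 10 to 260 in mature leaves and 1241 to 5112 and 265 to 2089 in old leaves, and 10 to 26 families changed. Where 1 library of a day is left, it is assumed to vary like the others. On the log2 scale the chloroplast share ranged from -0.266 to -0.194 and from -1.24 to -1.01, the mitochondrial share from 0.202 to 0.362 and from 0.213 to 0.351, the 21 nt share from -0.341 to -0.139 and from -1.20 to -0.874, and the 24 nt share from -0.0640 to 0.0967 and from -1.0 to -0.827.

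Of 7067 repeats of 191 values of named genes, 63 lost their call, 5 gained one and 0 changed direction; 29 of the losses came with set 1 alone and 25 with set 2 alone. For the 15 calls of microRNA families 54 of 330 repeats lost the call, and for named sequences 14 of 130 (DESeq2 gave no adjusted p for 2 of them). Removal of rRNA and tRNA reads was not run, since they are not labelled and the sequences were not matched to such genes. In the simulated small RNA, with 1 dispersion for all sequences, no set effect and 200 changed, changes of log2 1 were not called. The real data differ in these points, and miR158 was called at a change of -1.04 among the families. The simulation therefore does not set the limit of what can be called, but an absent call for a sequence still says little.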

Other observations

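The tests of read lengths, of the mitochondrial share and of other splits of the libraries in this part were chosen after the results were seen. Ethylene, jasmonate and cytokinin genes went both ways within each list. In mature against young leaves 9 of 15 ethylene genes rose, EIN3 from 31.2 to 80.1 FPKM, 3 fell, ACS6 from 48.1 to 15.6, and 3 did not pass (relative median 0.13, camera adjusted p = 0.95). In old against mature leaves 11 rose, ACS2 from 0.189 to 25.6 FPKM, 1 fell and 3 did not pass (relative median 0.51, camera adjusted p = 0.0228; adjusted p = 0.441 with an estimated correlation). Of 17 jasmonate genes 10 rose in mature leaves, LOX2 from 141 to 363 FPKM, 1 fell and 6 did not pass (relative median 0.41, camera adjusted p = 0.279). In old leaves 6 rose, JAZ1 from 18.1 to 150 FPKM, 6 fell, LOX2 to 169, and 5 did not pass, with a median of -0.11, a mean of 0.12 and a camera test pointing downwards (adjusted p = 0.398). Of 15 cytokinin genes 7 rose in mature leaves, AHK3 from 17.7 to 44.5 FPKM, 5 fell, ARR5 from 1.76 to 0.545, and 3 did not pass (median 0.26 as deposited, -0.156 after quantile normalization; camera, pointing downwards, adjusted p = 0.48). In old leaves 10 fell, ARR7 from 8.64 to 0.932 FPKM, and 5 rose, the cytokinin oxidase CKX5 from 2.92 to 56.1 (relative median -0.93, camera adjusted p = 0.0627).

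Regulators of leaf growth and of small RNAs changed in both directions. Of 10 leaf growth genes 6 rose in mature leaves, GRF1 from 1.57 to 4.94 FPKM, 2 fell, TCP4 from 17.2 to 9.78, and 2 did not pass (relative median 0.08, camera adjusted p = 0.977). In old leaves 7 fell, ANT from 0.471 to 0.0199 FPKM, 1 rose and 2 did not pass (relative median -0.59, camera adjusted p = 0.0508; 0.0272 with nuclear genes rescaled, 0.0264 after quantile normalization and 0.0277 without day 4). Of 19 genes of the small RNA machinery 10 rose in mature leaves, RDR1 from 2.43 to 10.4 FPKM, 3 fell and 6 did not pass (median 0.29 as deposited, -0.104 after quantile normalization; camera adjusted p = 0.48). In old leaves 9 fell, RDR6 from 5.64 to 1.53 FPKM and AGO4 from 8.51 to 3.05, 6 rose, SE from 12.2 to 20.5, and 4 did not pass (relative median -0.28, camera adjusted p = 0.225). Of 7 genes of alternative respiration 5 rose in mature leaves, AOX1A from 15.9 to 43.1 FPKM, and 2 did not pass (relative median 0.36, camera adjusted p = 0.239). In old leaves 5 rose, AOX1D from 0.762 ± 0.942 to 92.2 ± 53.3 FPKM, NDA1 fell from 52.7 to 13.6 and 1 did not pass (relative median 1.11, camera adjusted p = 0.152).

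Salicylic acid genes peaked before the end of the series, as a mean over the list of 1.84 in set 1 and 2.15 in set 2 at day 24, relative to each gene's mean, against 1.26 and 1.01 at day 30 and -2.32 and -1.42 at day 4. The day of the peak was noticed in the values and was not tested.

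The reads of 29 to 33 nt in old leaves came from few sequences. GCGCGCGACCTATACCCGGCCGTCGGGGC made up 0.421 ± 0.484% of listed reads in young, 6.22 ± 3.34% in mature and 14.8 ± 4.49% in old leaves, and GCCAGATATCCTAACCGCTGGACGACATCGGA 0.504%, 3.09% and 13.7 ± 5.18%. The 5 most abundant sequences held 61.7% of the 29 to 33 nt reads of old leaves and the 100 most abundant 94.1%, of 15709 listed. Without the 10 sequences most abundant over all lengths and libraries, the share of 29 to 33 nt reads rose by 1.21 from mature to old leaves (log2 scale, exact p = 0.0286). How many of those 10 are of 29 to 33 nt was not determined. The value therefore does not decide whether a few sequences carry the rise. Breakage into fragments of every length stays open: among reads of 18 to 28 nt those of 18, 19 and 25 to 28 nt rose from 34.6 ± 1.68% to 41.0 ± 3.34% (0.246 on the log2 scale, exact p = 0.0286), which breakage and a fall of 20 to 24 nt reads would both give. Size selection that varied at random between libraries is argued against by reads of 32 nt, the length that gained most in either set: picked in the other set, their share had a rank correlation with day of 1 in set 1 (exact p = 0.000397) and 0.893 in set 2 (exact p = 0.0123), while selection that differed by day stays open. Leaf age itself is a further candidate explanation that was not tested, and the source of the sequences was not determined.

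The rise of the mitochondria-encoded share from mature to old leaves cannot be told apart from the fall of the chloroplast-encoded share in the same sum: over the nuclear sum it was 0.134 on the log2 scale (exact permutation p = 0.23), which neither reaches 0 nor passes.

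The role of chance was examined by refitting other splits of the compared libraries alone, 12 of total RNA or 8 of small RNA. The real counts of these fits therefore differ from those of the fit to all libraries, which called 9406 genes higher and 3049 lower in mature leaves, 8807 higher and 4943 lower in old leaves, and 18 and 19 lists. In the total RNA only the real split of 100 gave as many genes. It gave 10571 in mature against young leaves (highest other 563) and 12777 in old against mature (highest other 7911). The median of the other splits was 0 genes in each comparison. Splits that mix the stages mostly call few genes, and these splits do not keep to the sets, so chance is not excluded. For the lists called in these fits chance cannot be excluded: 6 of 100 splits gave as many in mature against young (real 20, highest other 21) and 50 of 100 in old against mature (real 17, highest other 23). In the small RNA of mature against young leaves the real split called 0 sequences (edgeR), which all 35 splits reach by necessity, so the count says nothing about chance (highest other 90). For families 3 of 35 splits gave as many (5, highest other 8), so chance cannot be excluded. In old against mature leaves only the real split of 35 gave as many sequences (9828, highest other 0) and families (11, highest other 4). That is the smallest share 35 splits can give, and the splits do not keep to the sets. Splits that mix the stages again call few, so chance is not excluded.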
